A study of Mus musculus with 6 samples.

How the data were processed

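Articular cartilage was taken from knees and hips of 5-week-old mice and pooled, digested overnight in collagenase at 3 mg/ml, and the cells were grown with 10% serum for about 1 week per the growth protocol in the labels, or about 10 days per the series' design text. Per the labels, total RNA was extracted with Trizol, libraries were made with a stranded total RNA kit, and they were sequenced on an Illumina NextSeq with 75 cycles from each end. The submitters' processing notes name bcl2fastq, cutadapt 1.18, HISAT2 2.1.0, StringTie 1.3.5 and edgeR, and the build mm10, without roles. The annotation, the strand setting of the counting and the rule of the filter on low genes are not given in the sources used here.

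The deposited values are a signal per gene and library that the authors made by scaling read counts to TMM-normalized CPM and keeping 10189 genes, per the name of the table. In each library 100% of values were whole multiples of 1 step (tolerance 0.001 reads), so whole reads were recovered. The step was 0.382 to 0.762 CPM. A library's summed CPM can exceed that of plain CPM because TMM divides by an effective library size, which was 1312596 to 2620206. The fixed design had assumed plain CPM. The same log-scale test was used for this signal. In each row the second highest of the 6 values was at least 7.35 CPM, which describes the filter. Symbols were matched to GENCODE M21, an annotation of mm10, for 10116 genes (99.3%). Of the 6 column names, 5 matched the title of a sample, and the other, that of KO 3, differed from its title by 1 character (a letter O in place of a zero). 0 columns of values were left unmapped.

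The design, the gene lists, the rule for named genes and the alternatives, apart from those named as added, were set before the data were examined. The 3 KO and 3 wild-type samples were compared with limma 3.58.1 (R 4.3.3) with an intensity trend on log2(CPM + 0.5), two-sided, with Benjamini-Hochberg adjustment over all genes, and called at an adjusted p below 0.05. Recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16, with DESeq2 1.42.0 and with limma-voom as alternatives. They called 0, 26 and 0 genes higher and 2, 102 and 1 lower. Of 34 fixed gene lists, the 26 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. A list's shift is the mean log2 fold change of its members minus that of other genes. A member counts as higher or lower by the sign of its log2 fold change, that is by its mean on the log scale. No list call held with an estimated correlation, where the lowest adjusted p was 0.443. The directional test of fry, which asks whether a list's genes move on balance 1 way, called osteoblast markers and p53 targets (adjusted p = 0.0391 for each). Its mixed test, which asks whether they change in either direction, called 14 lists. Seed sites were searched in the longest annotated 3′ UTR of at least 20 bases (9622 genes) as matches to positions 2 to 8 of the miRNA, against genes with no match to positions 2 to 7. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps.

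Named genes followed a fixed rule: per direction the 12 largest changes past the threshold, with a mean of at least 1 CPM and no overlap between groups, or, with fewer, those and the genes of smallest p up to 6; a fixed set of miR-34a and cartilage genes; up to 4 members of smallest p per described list; and 4 seed site genes that were higher. Dll1 of the fixed set has no row in the table. S100a8, Mmp8, Malat1, Lyz2, Lcn2, Xist, Tsix and Agtrap were added after their values were seen. The lists of neutrophil, histone and ribosomal protein genes were also chosen after results were seen.

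The procedure was tested on simulated data: 10 sets of counts for the 10189 genes, drawn from the means and library sizes of these samples with 200 changed genes. Of genes changed 2-fold and 4-fold, limma recovered 5.8% and 61.7%, edgeR 5.2% and 61.1%, and DESeq2 19.6% and 76.3%. In sets with no change they called 0.3, 0.4 and 5.8 genes per set. The 200 changed genes were drawn from those with a mean of at least 10 CPM. A list of 27 genes at 1.5-fold was found in 10 of 10 sets, and a seed shift of 0.1 in 6 of 10. Both were counted as found at a camera p below 0.05 without adjustment over lists, unlike the fixed lists. Simulated genes vary independently, which real genes do not. Chi-square per degree of freedom between replicates was 5.83 to 27.8, so that no 2 libraries of 1 genotype were the same within sampling noise.

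Alternatives were the pseudocount, a filter, 2 other scalings, limma without trend, with robust empirical Bayes or with array weights, a block on the replicate number, leaving out each library, leaving out sex chromosome genes, the 3 tests of recovered reads, other thresholds, and other site and distance definitions. After the data were seen, 4 were added: genes with no gene on the opposite strand (5846 genes), a correction for GC content and transcript length, wild type 1 with KO 2 left out, and the macrophage list without S100a8 and S100a9. A covariate of Y-linked genes was not run, because 0 Y-linked genes of the list were analysed here. Shifts are given for the called lists and for the lists described by name. Of the 18 lists not called, 11 had the other sign in at least 1 setting.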

Results

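Gene expression was measured by RNA-seq of total RNA in primary chondrocytes, the cells of cartilage, from 5-week-old C57BL/6 mice that lacked both copies of the microRNA gene Mir34a (miR-34a KO) or carried the normal gene (wild type). Each genotype had 3 samples. The cells came from articular cartilage of knees and hips and were grown in culture before RNA extraction. The deposited table held 10189 genes as TMM-normalized CPM, read counts scaled to library size, from which 989217 to 5266617 reads per library were recovered. Wild type 1 had the highest total, and 59.1% of its reads lay on Rn45s, a ribosomal RNA precursor, and 18.9% on Lars2. Without Rn45s, Lars2 and Mir6236, the libraries held 947081 to 1772185 reads. Tsix, which lies antisense to Xist, was 8.12 to 16.5 times Xist in 6 of 6 libraries. Genes opposite coding exons of other genes had a median log2 fold change of −0.21, against 0.07 for genes with no opposite gene. The strand setting of the counting is not given in the sources used here, so the values of all genes named below are uncertain, those with no opposite gene included. The titles carry a different code for each sample. The labels do not say what the codes mark, or whether the samples of a genotype came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Values below are the mean ± SD in CPM over 3 libraries per genotype, and log2 fold changes are KO against wild type on the log2(CPM + 0.5) scale, which understates the change of low genes.

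The comparison asked which genes and pathways differ in chondrocytes without miR-34a. Mir34a lies on chromosome 4 at 150068454 to 150068555 (mm10). It has no row in the table, so the genotype labels could not be checked against the deleted gene. Invs, which encodes inversin, a protein of the primary cilium, was the gene that passed with limma: it had 220.1 ± 21.7 CPM (SD, n = 3) in wild type and 50.1 ± 3.90 CPM (SD, n = 3) in KO. Its log2 fold change was −2.12 (SE 0.18, limma adjusted p = 0.00873). It lies on chromosome 4 at 48279760 to 48431954, and 226 of its exon bases overlap exons of Tex10 on the opposite strand. Reads of Invs and Tex10 cannot be told apart here. Limma called 0 genes higher and 1 gene lower in KO at an adjusted p below 0.05. At an unadjusted p below 0.05, 473 genes were higher and 652 lower. Of these, 35 higher and 236 lower lie opposite coding exons, while 298 higher and 242 lower have no opposite gene. The excess of lower genes turned without wild type 2 (402 higher and 384 lower) and without wild type 3 (475 and 401). It stayed when any other library was left out, and with no trend the counts were 510 and 505. The quasi-likelihood test of edgeR on the recovered reads called 0 higher and 2 lower (Invs and S100a9), limma-voom 0 and 1, and DESeq2 26 and 102. The Invs call ended without wild type 1 (limma adjusted p = 0.160), with wild type 1 and KO 2 left out (0.0787) and with a block on the replicate number (0.123). The counts higher and lower were 0 and 0 without wild type 1, 3 and 1 without wild type 2, 1 and 2 without wild type 3, 0 and 4 without KO 1, 7 and 25 without KO 2, and 0 and 3 without KO 3. In simulated data of this size, limma recovered 5.8% of genes changed 2-fold and 61.7% of those changed 4-fold, none of them from the genes of lowest mean.

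The genes of smallest p among those higher in KO did not pass the adjusted threshold with limma. DESeq2 called Grem1, Col11a2 and Ephx1 among them, and limma with robust empirical Bayes called Grem1. Grem1, which encodes the BMP antagonist gremlin 1, had 31.6 ± 10.3 CPM in wild type and 148 ± 32.4 CPM in KO (log2 fold change 2.25, SE 0.30, limma adjusted p = 0.0701). Col11a2 and Col9a2, which encode chains of the minor cartilage collagens, had log2 fold changes of 1.94 (SE 0.34) and 1.75 (SE 0.35). Panx3, a pannexin channel of skeletal cells, had 2.05 (SE 0.39), the receptor tyrosine kinase gene Epha2 had 2.05 (SE 0.39), and Ephx1, which encodes microsomal epoxide hydrolase, had 1.31 (SE 0.25). Among genes lower in KO, S100a9, which encodes a calcium-binding protein abundant in neutrophils, had 44.2 ± 7.29 CPM in wild type and 0 reads in each KO library. Against a floor of 3 reads over the 3 KO libraries it was at least 92.8-fold lower (limma adjusted p = 0.0701). The floor covers counting error only. Zcwpw1 had a log2 fold change of −2.02 (SE 0.27), Ap3m1 −1.44 (SE 0.19), Gse1 −1.37 (SE 0.20) and Sorbs2os −1.95 (SE 0.31). The main limma test called none of these last 4 genes, DESeq2 called all 4, and limma with robust empirical Bayes called Zcwpw1 and Ap3m1. They share 468, 571, 134 and 1051 exon bases with genes on the opposite strand (Pilra, Vcl, 1700016A09Rik and Sorbs2), whose reads cannot be told apart from theirs here.

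Cartilage genes were higher in KO as a group. Of 27 measured chondrocyte markers, 23 had higher means in KO and 4 lower, and 5 were higher with limma when adjusted over the list alone (Col11a2, Col9a2, Col9a3, Fmod and Acan). Over all genes, limma, edgeR and limma-voom called 0 of the 27 and DESeq2 3 (Acan, Col11a2 and Fmod), and 9 were higher at an unadjusted limma p below 0.05. Acan, which encodes aggrecan, the main cartilage proteoglycan, had 84.6 ± 8.82 CPM in wild type and 207 ± 100.5 CPM in KO. Col9a3 shares 234 exon bases with Tcfl5 on the opposite strand. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, had 189 ± 30.3 and 489.5 ± 225 CPM. The list's mean log2 fold change was 0.74 above that of other genes (camera adjusted p = 2.86e-06). With an estimated correlation, the adjusted p was 0.50. The shift was 0.47 without KO 1, the library with the highest chondrocyte score (0.91) and the lowest macrophage score (−2.01). Mural marker scores, −0.95 to 0.10 in KO and 0.32 to 0.95 in wild type, were lower in each KO library. Col2a1, the main collagen gene of cartilage, had a log2 fold change of 0.50 (SE 0.26, limma adjusted p = 0.506) and Sox9, the master regulator of chondrocytes, 0.65 (SE 0.39, limma adjusted p = 0.547). Without KO 1, Col2a1 had 0.28 and Sox9 0.42, and without wild type 3 Col2a1 had 0.31. Prg4, which encodes lubricin, had 0.24 (SE 0.28), and the aggrecanase gene Adamts5 −0.05 (SE 0.25). Neither passed with limma. Prg4 was −0.02 without wild type 2, and Adamts5 was 0.09 without wild type 1, 0.02 without wild type 3 and 0.12 without KO 3.

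Markers of hypertrophic chondrocytes and osteoblasts were also higher in KO as groups, though not each marker. All 7 measured osteoblast markers had higher means in KO, 1 of them (Ibsp) past the limma threshold when adjusted over the list alone. Adjusted over all genes, limma, edgeR and limma-voom called 0 of the 7, DESeq2 called Ibsp, limma without a trend called Bglap and Bglap2, and 2 were higher at an unadjusted limma p below 0.05. Ibsp, which encodes bone sialoprotein, had 1014 ± 582 CPM in wild type and 3287 ± 571 CPM in KO. Bglap and Bglap2, near-identical copies of the osteocalcin gene whose reads are uncertain, had 0 reads in the 3 wild-type libraries and were at least 12.3-fold and at least 15.1-fold higher in KO against a floor of 3 reads over the group. The median log2 fold change of the 7 was 0.95, while Bglap and Bglap2 had 4.01 (SE 1.91) and 4.35 (SE 1.68) and weigh most on the mean. With 0 reads in wild type, both could enter the filtered table only through their KO values. The second highest value of Bglap, 7.35 CPM, was the lowest of any row. The list was shifted by 1.66 (camera adjusted p = 0.00575). An estimated correlation gave an adjusted p of 0.50. Without KO 1 the adjusted p was 0.0786. Of 13 hypertrophic markers, 10 had higher means in KO, and Ibsp and Panx3 passed with limma when adjusted over the list alone. Over all genes, limma, edgeR and limma-voom called 0 of the 13 and DESeq2 called Ibsp, and 4 were higher at an unadjusted limma p below 0.05. The list was shifted by 0.43 (camera adjusted p = 0.0182). With an estimated correlation, the adjusted p was 0.443. At the preset correlation it was 0.0742 without wild type 1, 0.0525 without wild type 3, 0.269 without KO 2 and 0.399 without wild type 1 and KO 2 together (shift 0.27). Ibsp, Sp7 and Alpl stand in both lists. The collagenase gene Mmp13 had a log2 fold change of 0.72 (SE 0.28, limma adjusted p = 0.394) and Col10a1, the collagen gene of hypertrophic cartilage, 0.31 (SE 0.39), which was −0.21 without KO 2.

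**Figure D1:**
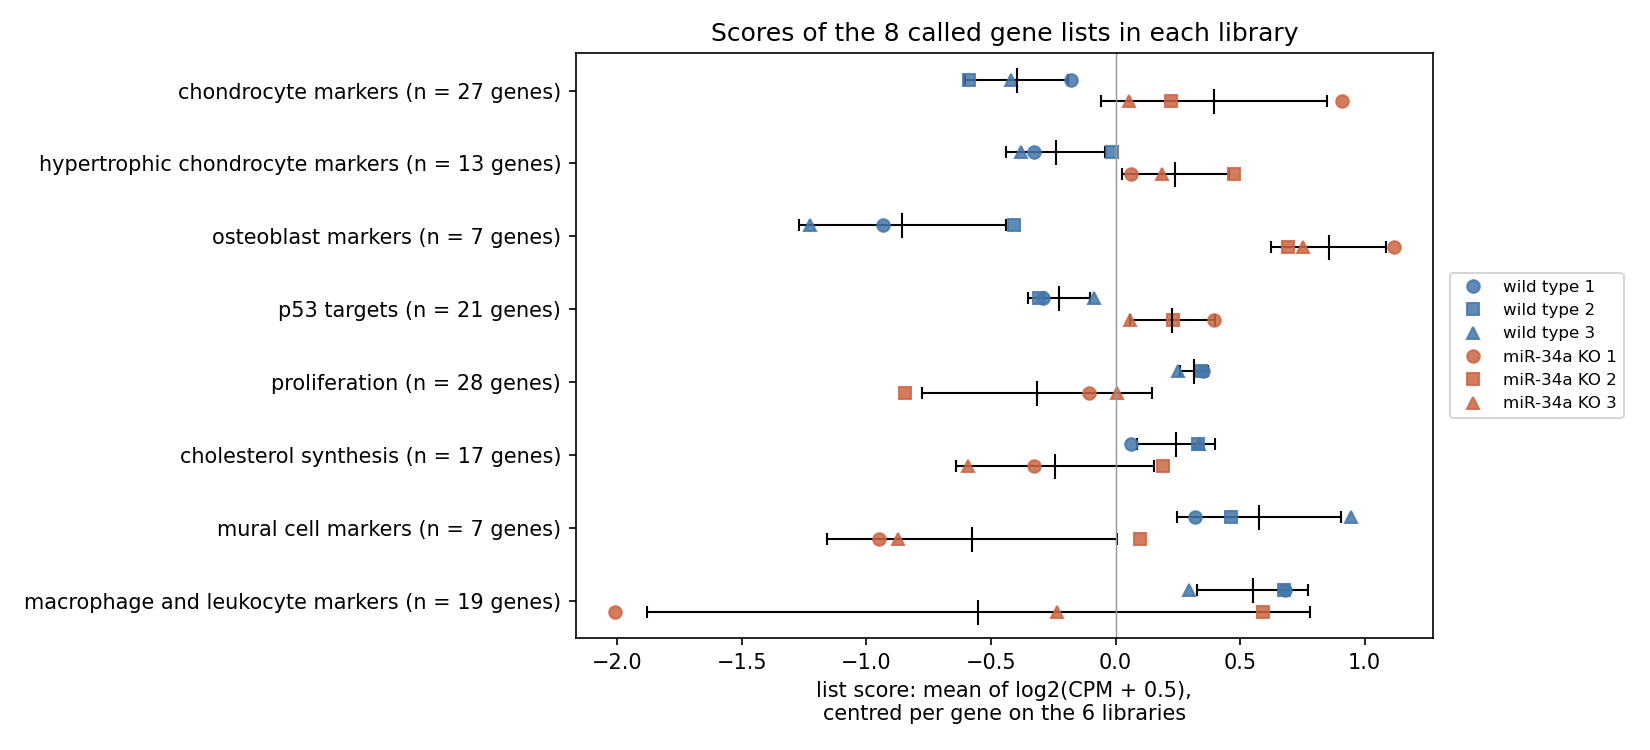
Scores of the 8 called gene lists in each library (points), with the mean and SD of 3 libraries per genotype (black bars). The horizontal axis is the mean of log2(CPM + 0.5) over the members, centred per gene on the 6 libraries, and the proliferation scores were 0.25 to 0.35 in wild type and −0.85 to 0.01 in KO.

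Cell cycle genes were lower in KO as a group. Of 28 proliferation genes, 25 had lower means in KO, and 7 were lower with limma when adjusted over the list alone. Adjusted over all genes, limma, edgeR and limma-voom called 0 of the 28 and DESeq2 4 (Cenpe, Top2a, Ccna2 and Mki67), and 11 were lower at an unadjusted limma p below 0.05. Cenpe, a kinetochore motor gene, had 98.7 ± 24.5 CPM in wild type and 31.4 ± 5.64 CPM in KO. Top2a, which encodes the DNA topoisomerase of dividing cells, had 314 ± 11.9 and 185 ± 22.9 CPM, and the proliferation marker Mki67 had 667 ± 88.8 and 375 ± 93.9 CPM. Ccna2, which encodes cyclin A2, had 430.5 ± 40.1 and 263 ± 33.4 CPM, and 510 of its exon bases overlap Exosc9 on the opposite strand. The list was shifted by −0.69 (camera adjusted p = 1.34e-08). An estimated correlation gave an adjusted p of 0.50. The shift was −0.41 without KO 2, the library with the lowest proliferation score (−0.85), and −0.40 without KO 2 and wild type 1. KO 2 also had the highest macrophage score among KO libraries (0.59) and lay apart from the other 5 libraries on the second principal component (−56.5, against 4.74 to 16.7). Of 21 targets of the tumour suppressor p53, 19 had higher means in KO, and 0 passed with limma when adjusted over the list alone. Over all genes, limma, edgeR, limma-voom and DESeq2 each called 0 of the 21, and 4 were higher at an unadjusted limma p below 0.05. Of these targets, Trp53inp1, Ccng1 and Mdm2 had log2 fold changes of 0.89 (SE 0.27), 0.63 (SE 0.20) and 0.56 (SE 0.21), and Ei24 had 2.82 (SE 1.09), which was 1.49 without wild type 2. The p53 list was shifted by 0.40 (camera adjusted p = 0.00908). With an estimated correlation, the adjusted p was 0.443. The shift was 0.26 among genes with no opposite-strand gene, and the call ended without wild type 1 and KO 2 together (camera adjusted p = 0.0521). Cdkn1a, which encodes the cell cycle inhibitor p21 and is a p53 target, had 0.09 (SE 0.31), which was −0.07 without wild type 3 and −0.13 without KO 1.

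**Figure D2:**
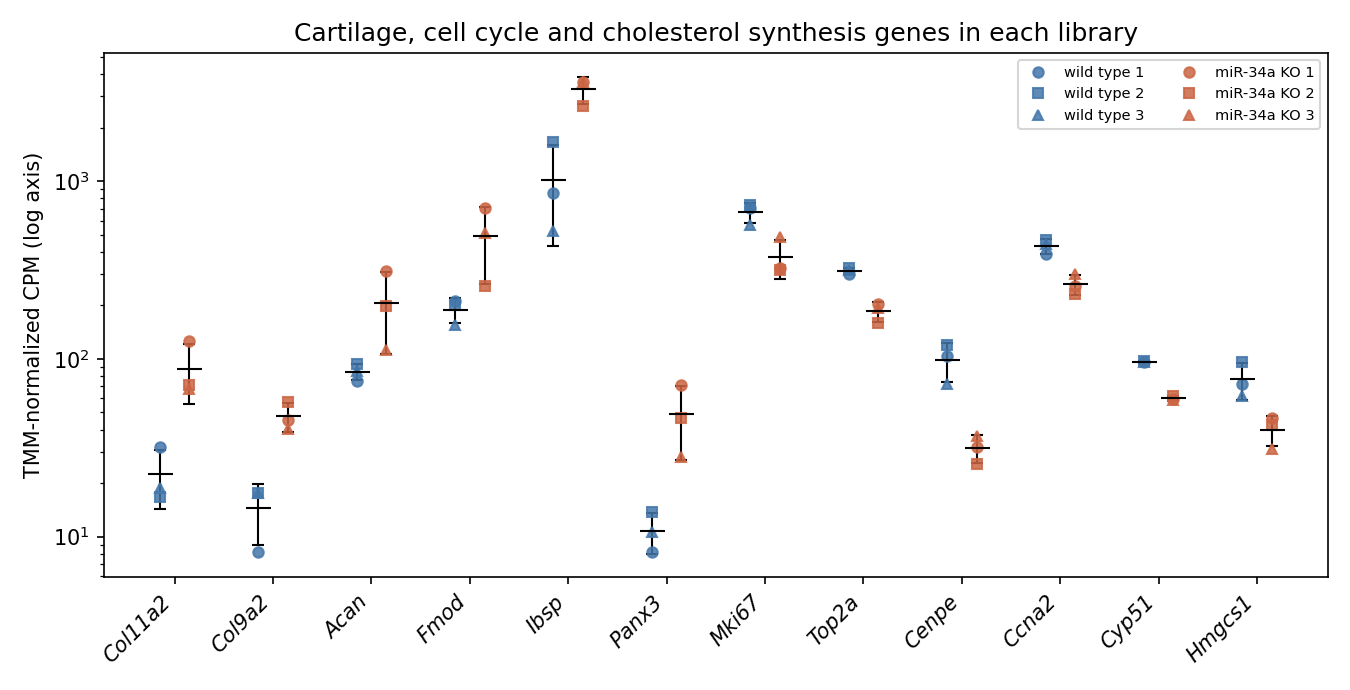
CPM of cartilage, cell cycle and cholesterol synthesis genes in each library (points, log axis), with the mean and SD of 3 libraries per genotype (black bars). Acan was 75.4 to 92.9 CPM in wild type and 112 to 312 CPM in KO, and Cyp51 was 95.5 to 97.5 CPM in wild type and 58.7 to 61.7 CPM in KO.

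Genes of cholesterol synthesis were lower in KO as a group. Of 17 measured genes, 12 had lower means in KO, and 3 (Cyp51, Hmgcs1 and Idi1) were lower with limma when adjusted over the list alone. Adjusted over all genes, limma, edgeR, limma-voom and DESeq2 each called 0 of the 17, and 7 were lower at an unadjusted limma p below 0.05. The score of KO 2, 0.19, lay within the wild-type range of 0.06 to 0.33, and those of KO 1 and KO 3 were −0.33 and −0.59. Cyp51, a sterol demethylase gene, had 96.2 ± 1.15 CPM in wild type and 59.9 ± 1.63 CPM in KO. Hmgcs1, which encodes the synthase before HMG-CoA reductase, had 76.6 ± 17.6 and 40.0 ± 7.83 CPM, and Idi1 had 22.9 ± 4.73 and 8.50 ± 2.68 CPM. Hmgcs1 and Idi1 share 557 and 218 exon bases with Gm48342 and Gm48574 on the opposite strand. Insig1 had a log2 fold change of −0.92 (SE 0.30). The list was shifted by −0.54 (camera adjusted p = 8.56e-04), and by −0.85 without wild type 1 and KO 2. Among genes with no opposite-strand gene it was −0.40 (camera adjusted p = 0.00744), and the weakest shift of any alternative was −0.37. An estimated correlation gave an adjusted p of 0.50.

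The lists of markers of macrophages and leukocytes and of mural cells, the smooth muscle cells and pericytes of vessel walls, had lower means in KO. Of 19 macrophage and leukocyte markers, 16 had lower means in KO, and Mrc1, S100a8 and S100a9 were lower with limma when adjusted over the list alone. Over all genes, limma and limma-voom called 0 of the 19, edgeR called S100a9, DESeq2 called Mrc1, limma without a trend called S100a8 and S100a9, and 3 were lower at an unadjusted limma p below 0.05. Mrc1, the mannose receptor gene of macrophages, had 493 ± 159 CPM in wild type and 175 ± 98.2 CPM in KO. Itgam had a log2 fold change of −0.99 (SE 0.62), which was −0.16 without KO 1 and −1.71 without KO 2, and Mrc1 was −1.05 without KO 1. The list was shifted by −1.16 (camera adjusted p = 0.00207). With an estimated correlation, the adjusted p was 0.727. The members that changed most were S100a8 and S100a9, which a list of neutrophil markers also holds. Without them, a choice made after their values were seen, the shift of the other 17 was −0.59 (camera adjusted p = 0.0437, and 0.936 with an estimated correlation). For these 17 it was 0.22 without KO 1 (camera adjusted p = 0.150) and −1.22 without KO 2 (6.74e-07). The call of the 17 ended without wild type 1 (0.134) and without wild type 2 (0.126). The KO libraries differed widely: the scores of the 19 were −2.01, 0.59 and −0.23, against 0.29 to 0.68 in wild type, and those of the 17 were −1.90, 1.014 and 0.09, against 0.01 to 0.40. Lyz2, a lysozyme gene of macrophages, had 594, 12165 and 1757 CPM in KO 1, KO 2 and KO 3. Without KO 1 the shift of the 19 was −0.44 (camera adjusted p = 0.877). With edgeR values the adjusted p was 0.0616. Of 7 mural markers, 6 had lower means in KO. Cnn1 and Lmod1, genes of the contractile apparatus, were lower with limma when adjusted over the list alone, with log2 fold changes of −1.93 (SE 0.43) and −1.44 (SE 0.51), and Cspg4, a pericyte proteoglycan gene, was higher with 1.12 (SE 0.34). Over all genes, limma, edgeR, limma-voom and DESeq2 each called 0 of the 7, and 1 was higher and 4 lower at an unadjusted limma p below 0.05. Myh11, a smooth muscle myosin gene, had −1.48 (SE 0.58), which was −0.90 without wild type 3. The mural list was shifted by −1.21 (camera adjusted p = 0.0182). An estimated correlation gave an adjusted p of 0.443. At the preset correlation it was 0.120 without wild type 3 and 0.0523 without KO 1.

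The list of dedifferentiation and fibroblast markers, genes that cultured chondrocytes can gain, was not called by camera (shift −0.31, adjusted p = 0.401), while the mixed test of fry called it (adjusted p = 0.00992). Its shift was −0.11 with quantile normalization. Of its 18 measured genes, 6 were lower and 2 higher with limma when adjusted over the list alone. Adjusted over all genes, limma, edgeR and limma-voom called 0 of them and DESeq2 3 lower and 1 higher (Fbn1, Acta2 and Col3a1, and Lum), and 7 were lower and 3 higher at an unadjusted limma p below 0.05. The contractile gene Acta2 had 317 ± 84.9 CPM in wild type and 112 ± 70.6 CPM in KO, and Fbn1, which encodes fibrillin 1 and shares 1046 exon bases with Gm9913 on the opposite strand, had 411 ± 120.5 and 115 ± 47.4 CPM. Col3a1, the type III collagen gene, had 3732 ± 832 and 1944 ± 354 CPM, and Col1a1, a type I collagen gene, 419.6 ± 68.3 and 287 ± 33.4 CPM. Lum, which encodes the proteoglycan lumican, was higher, with 373 ± 78.2 and 713 ± 201 CPM.

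No shift of the known targets of miR-34a-5p was called. Of 45 measured targets, 22 had higher means in KO and 23 lower, and 0 passed with limma when adjusted over the list alone. Over all genes, limma, edgeR, limma-voom and DESeq2 each called 0 of the 45, and 1 was higher at an unadjusted limma p below 0.05. The mean shift was −0.02 (camera adjusted p = 0.911), the median −0.0033, and the direction that camera gave was up. Gas1 had a log2 fold change of 1.02 (SE 0.34), Birc5 −1.05 (SE 0.47), Hdac1 −0.59 (SE 0.28) and Ppp1r10 0.54 (SE 0.27). Gas1 was 0.65 without wild type 2 and Birc5 −0.67 without KO 2. Notch1 had −0.16 (SE 0.30) and was 0.15 without wild type 2, the deacetylase gene Sirt1 −0.28 (SE 0.27), and the survival gene Bcl2 0.45 (SE 0.41). None of the 3 passed with limma. Sirt1 was −0.43 without wild type 1 and −0.0059 without wild type 3, and Bcl2 was 0.75 without wild type 1, 0.27 without wild type 3 and 0.26 without KO 1. Notch1, Bcl2 and Gas1 share 1068, 558 and 589 exon bases with genes on the opposite strand, and Prg4, Cdkn1a, Ei24, Numb and Col10a1 share 204, 273, 323, 166 and 18. Of 13 Notch pathway genes, 5 had higher and 8 lower means, and 0 passed with limma when adjusted over the list alone (shift −0.28, camera adjusted p = 0.843). In the 13 genes, limma, edgeR, limma-voom and DESeq2 each called 0 over all genes, and 0 had an unadjusted limma p below 0.05. Rbpj, the transcription factor of the pathway, had 0.49 (SE 0.24), Jag1 −0.94 (SE 0.51), Numb 0.83 (SE 0.47) and Lfng −1.92 (SE 1.22). Rbpj was 0.29 without KO 2, Jag1 −0.55 without KO 1, Numb 0.41 without wild type 3, and Lfng −0.57 without KO 1 and −3.33 without KO 3. The Notch shift was 0.04 without KO 1.

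Genes whose longest 3′ UTR holds a match to the miR-34a-5p seed (CACTGCC) showed no shift past camera or the directional test of fry. The 1710 genes with a site had a mean log2 fold change of 0.08 and the 6215 genes without the core match 0.07, a difference of 0.0068 (camera p = 0.849, and p = 0.607 with an estimated correlation). Of 89 other 7-mers of the same base composition that hold no CG, 66 gave a difference at or above this. Leaving out 7-mers that hold a CG was not part of the fixed design. Among random genes matched on UTR length and expression, the mean of the site genes lay at percentile 7.86 of 10000 draws. At an unadjusted p below 0.05, 90 site genes were higher and 96 lower with limma. Adjusted over all genes, limma, edgeR and limma-voom called 0 of them, limma with robust empirical Bayes called Grem1, and DESeq2 called 3 higher and 17 lower. The site genes of smallest p among those higher in KO were Grem1, Crebrf, C1rl and Edil3, which did not pass with limma. DESeq2 called Grem1, Crebrf and Edil3. Crebrf had 32.0 ± 4.21 CPM in wild type and 73.8 ± 14.6 CPM in KO, C1rl 5.97 ± 3.02 and 22.8 ± 5.48 CPM, and Edil3 65.9 ± 3.36 and 157 ± 66.4 CPM.

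Genes within 5 Mb of Mir34a on chromosome 4 showed no excess of changed genes past the test. Of 62 measured genes, limma, edgeR, limma-voom and DESeq2 each called 0 over all genes, limma called 0 adjusted over these genes alone, and 4 had an unadjusted p below 0.05, or 6.45% against 11.1% of other genes (two-sided Fisher exact p = 0.312). Agtrap had the smallest p, with a log2 fold change of 1.00 (SE 0.28). Within 10 Mb, limma called 0 of 119 genes, and 7 had an unadjusted p below 0.05 (5.88% against 11.1%, two-sided Fisher exact p = 0.0767). The smallest p there was that of Epha2, named above among the genes higher in KO. Limma called Epha2 without KO 2 (adjusted p = 0.0395).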

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

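The alternatives on genes without an opposite-strand gene, on GC content and length, on wild type 1 with KO 2 left out, and on the macrophage list without S100a8 and S100a9 were chosen after the data were seen. The cause was not tested for any change given here, except that fewer samples or genes were tested where some were left out.

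The count of genes higher in KO, 0 at first, was 7 with no trend, 1 with robust empirical Bayes, 26 with DESeq2, 1 at an adjusted p below 0.1, and 0 to 7 with each library left out. The count lower, 1 at first, was 2 with a pseudocount of 1, 3 with no trend, 3 with robust empirical Bayes, 2 with edgeR, 102 with DESeq2, 4 at an adjusted p below 0.1, 0 among genes with no opposite-strand gene, 2 with wild type 1 and KO 2 left out, and 0 to 25 with each library left out. With the replicate block it was 0. Deviations of samples with the same replicate number correlated weakly (0.03, 0.08 and −0.06). Wild type 2 and KO 2 were each other's best match, and the other numbers did not match in both directions. With 3 samples per group, these values cannot tell whether the numbers mark pairs. The block left 8 lists called.

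The count of called lists was 8, 0 with an estimated correlation and 5 to 10 with each library left out. The shift of known targets turned to 0.024 with quantile normalization and 0.043 with wild type 1 and KO 2 left out, and was −0.096 to 0.056 with each library left out. The seed shift was −0.023 after the GC and length correction, −0.012 for genes with at least 2 sites, and 0.00079 to 0.0128 with each library left out. With wild type 1 and KO 2 left out, the hypertrophic and p53 lists were no longer called (adjusted p = 0.399 and 0.0521). Among genes turning sign, Adamts5 was 0.051 with quantile normalization, 0.087 with both libraries left out and −0.26 to 0.12 with each left out. Col10a1 was −0.12 with both left out and −0.21 to 0.60 with each. With each left out, Notch1 was −0.44 to 0.15, Prg4 −0.024 to 0.51, Cdkn1a −0.13 to 0.24 and the Notch list −0.45 to 0.039. The 8 called lists kept their direction in the 23 alternatives run on each. Without S100a8 and S100a9 the macrophage list was −0.59 (adjusted p = 0.0437, and 0.936 with an estimated correlation). Its call then ended without wild type 1 (0.134) and without wild type 2 (0.126). The shift turned to 0.22 without KO 1 and was −1.22 without KO 2. Depth limits low genes: 1 read was worth 0.382 to 0.762 CPM.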

Other observations

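The tests of explanations in this part were chosen after the results were seen, as were the histone, ribosomal protein and neutrophil lists and the genes S100a8, Mmp8, Malat1, Lyz2, Lcn2, Xist and Tsix. Histone genes were lower in KO as a group: 57 of 58 had lower means (shift −0.85, camera p = 8.53e-20, and p = 0.153 with an estimated correlation). The histone score of KO 3, 0.29, lay within the wild-type range of 0.21 to 0.63, and those of KO 1 and KO 2 were −0.76 and −0.71. Of 80 ribosomal protein genes, 39 had higher and 41 lower means (shift −0.0075, camera adjusted p = 0.633). Malat1, an abundant nuclear RNA, had 4017 ± 250 CPM in wild type and 9262 ± 3603 CPM in KO and shares 453 exon bases with Gm37376 on the opposite strand. On the first 2 principal components, with 32.1% and 22.1% of the variance, KO 2 lay apart on the second (−56.5, against 4.74 to 16.7).

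The other fixed lists were not called by camera or by the directional test of fry, while the mixed test of fry called 6 of them: circadian, collagen, dedifferentiation, TGF-beta and BMP, matrix protease and proteoglycan genes. The camera adjusted p lay between 0.196 and 0.935 for 18 lists, which included autophagy, collagens, matrix proteases, proteoglycans, TGF-beta and BMP, Wnt, hypoxia, interferon, inflammatory, heat shock, circadian, limb patterning, adipocyte, endothelial and synovial lists. The mean, median and camera direction differed in sign for circadian, interferon, Wnt and known target genes. Inflammatory and interferon lists were called without wild type 2 (adjusted p = 0.0179 and 0.00874), and limb patterning genes without KO 2 (0.0324) and without KO 2 and wild type 1 (0.0429). Lists of sex-linked genes (2 measured) and of C57BL/6 substrain-variable genes (4 measured) were too short to test. Sex-linked scores were −0.36 to −0.07 in KO and 0.14 to 0.20 in wild type. Substrain scores were 0.31 to 0.51 in KO and −0.86 to 0.12 in wild type. Of these genes, 2 and 2 share exon bases with opposite-strand genes. Whether the groups differed in sex or substrain was not tested, so genotype may not be their only difference.

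Many abundant rows lie opposite other genes. Of the 200 most abundant rows, 103 (51.5%) had coding exons on the opposite strand, against 15.2% of the others (Fisher exact p = 3.691e-32), and Tsix, the antisense partner of Xist, was 8.12 to 16.5 times Xist in 6 of 6 libraries. Counting without regard to strand would not give Tsix 8.123 times Xist or more, while counting on the strand opposite to the transcript may account for both values, since the kit marks strand, so that the row of Invs, the gene that limma called, could hold reads of Tex10 and rows with no opposite gene stray reads. The 1606 rows opposite coding exons had a median log2 fold change of −0.21, against 0.07 for rows with no opposite gene. Whether that reflects libraries differing in strand purity cannot be told apart from genotype: the difference between the classes changed by −0.2811 from wild type to KO, wild type 1 (−0.03) and KO 3 (−0.01) overlapped, and libraries of 1 genotype differed by up to 0.23.

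The proliferation list was lower and the chondrocyte list higher in KO. Reads from opposite-strand genes as the whole cause are argued against by shifts of −0.8174 and 0.893 among genes with no opposite gene, and GC content and transcript length by shifts of −0.693 and 0.7315 after correction. A larger share of all other cell types in wild type was first counted as argued against, because mural scores were lower and the osteoblast score 1.711 higher in KO, both with no overlap between the groups. Since 3 of the 7 osteoblast markers also stand on a chondrocyte list, the test was replaced after that value was seen. First it used the others with reads in every library, a filter that the change itself decides. Then it used the other 4. Their score was 2.162 higher in KO with no overlap, but the mean over the 4 was within 2 SE of 0 (SE 1.17). That mean was carried by Bglap and Bglap2, near-identical copies at 0 reads in wild type. The bound of 2 SE was set with these values known, and without it the test would have counted against this explanation. The test therefore cannot decide, and the explanation stays open. Loss of miR-34a may contribute and stays open (p = 0.08958 for the proliferation and 0.1301 for the chondrocyte list with an estimated correlation), as do a change in growth rate and in single cell types, and the 10 splits of the 6 samples are too few for a share under 0.05.

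S100a8 and S100a9 had 0 reads in each KO library, S100a8 at least 44.5-fold lower than in wild type against 3 reads over the group. Macrophage content at a ratio of S100a9 to Lyz2 no lower than in wild type is argued against. From Lyz2 and the lowest wild-type ratio, 296.2 S100a9 reads were predicted over the 3 KO libraries, and 0 were seen. Of the predicted reads, 251.4 were in KO 2, 15.76 in KO 1 and 29.09 in KO 3. The test does not cover macrophages with a lower ratio. Neutrophils in the wild-type cultures may be a source and stay open, with Mmp8, a neutrophil collagenase gene, at a log2 fold change of −2.042. Mmp8 did not fall to 0 as S100a8 and S100a9 did: it had 83 reads in wild type and 24 in KO. Lcn2, which chondrocytes can express, had 315, 101 and 113 CPM in wild type and 214, 91.6 and 71.0 CPM in KO. Of 18 neutrophil genes, 4 were measured, S100a8 and S100a9 among them, and each had a lower mean in KO (camera adjusted p = 9.48e-06, and p = 0.0101 with an estimated correlation), on a list chosen because of this pattern.

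For the other results, the same 10 splits are too few to give a share under 0.05. The real value and the highest of the other splits were 1 and 0 genes called, 1125 and 559 genes at an unadjusted p below 0.05, 8 and 11 lists called, 0 and 0 neighbours of Mir34a called, and shifts without sign of 0.02 and 0.14 for known targets, 0.0068 and 0.0148 for seed site genes, 0.69 and 0.51 for the proliferation list and 0.74 and 0.61 for the chondrocyte list. The number of splits as large as the real one was 1, 1, 2, 10, 9, 4, 1 and 1 in that order. Each of the other splits, which mix the genotypes, also called lists with camera at the preset correlation, 3 at the fewest.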
